A study of Mus musculus with 61 samples.

How the data were processed

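Polyadenylated RNA of mouse MII oocytes and in vitro fertilised embryos was measured in 47 libraries, per the labels. Oocytes and embryos were labelled with 2 mM 4SU for 6 h, their RNA was alkylated with iodoacetamide, and libraries followed a modified Smart-seq2 protocol with oligo-dT priming. For the 0-6hpi window, sperm and cumulus-oocyte complexes were incubated with 4SU. The 61 samples also include 14 of chromatin accessibility, which were not used.

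The deposited tables hold, per the file headers, read counts per gene, which are whole numbers but for 1 value. That value, a fraction in a damaged record (gene Nyx) that was left out, is in the deposited 90-96hpi replicate 3 column, which was therefore treated like expected counts and rounded; its other values are whole. The authors' notes name Trim Galore 0.6.10, STAR 2.7.10a and SAMtools 1.12, with Bowtie2 2.4.2, Picard 2.20.4 and deepTools 3.5.4, and the mouse build mm10. Which tool counted reads, the strand that was counted, and whether reads were parted by T-to-C conversions are not stated. The table of embryo numbers is held in part, and its last, incomplete record was left out.

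Groups and replicates were taken from the sample titles. The windows gave 24552 genes (16234 tested) in 30 libraries, the genotypes 22911 genes (16694 tested) in 11 libraries, and the embryo numbers 32370 records (9132 genes tested) in 6 libraries. The mean total was 14.8 ± 0.777 M reads in the libraries labelled KO, 18.8 ± 1.01 M reads in the controls, 18.2 ± 1.14 M reads in mKO and 22.4 ± 0.846 M reads in pKO. How replicates were obtained is not stated, so p-values measure the spread between these libraries.

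Each experiment was fitted with edgeR 4.0.16 in R 4.3.3 (filterByExpr with a minimum count of 10 and a minimum total of 15, TMM factors, robust quasi-likelihood F-test). Genes were called at a Benjamini-Hochberg adjusted p below 0.05, with no fold minimum, and all tests are two-sided. The SE of a log2 fold change is its size divided by the square root of F. Levels are CPM from the TMM-scaled totals.

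Before the data were examined, 22 gene lists, the pairwise comparisons, the alternatives and the rule for naming genes were set. Lists were tested with camera (limma 3.58.1, preset correlation 0.01) against the other genes, with an estimated correlation as an alternative, and with fry, which tests a list against no net change. The adjustment covers all lists and contrasts of an experiment. Sets of genes that rise or fall at least 2-fold between windows were tested in the genotype contrasts in the same way. Overlap between contrasts that share controls was set against 20 simulations of unchanged groups.

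The naming rule took Klf17 first. It then took genes with a mean of at least 20 CPM in the higher group, an adjusted p below 0.05, no overlap between the libraries of both groups (which chance gives 10% of genes in a comparison of 3 with 3), and a symbol other than Gm or 2 letters with digits alone, Rik, -ps, mt- or a bare Ensembl ID; clone names such as AC160063.1 pass. By log2 fold change it named the 4 highest and 4 lowest per window step, 12 and 12 for KO against control, 6 and 6 for mKO and pKO, and 3 and 3 per embryo contrast. For each list described, the rule allows up to 4 members with the smallest adjusted p, of which the first 2 are printed. That number, and the lists described (each list that camera called in the windows and embryo numbers, and all 22 for KO against control), were set after results were seen. Folds against a group with at most 3 reads are not given. Results of some genes that the rule selects are not reported here.

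Alternatives were DESeq2 1.42.0 (Wald test), DESeq2 size factors, total count scaling, no low-count filter, a replicate block, a fit of only the 2 groups, a minimum absolute log2 fold change of 1, and each library left out in turn. Thinning to one depth, leaving out mitochondrial genes, and the mitochondrial share as a covariate were added after the data were seen. On simulated data with 100 genes changed 2-fold and 100 changed 4-fold, edgeR recovered 73% and 99% for 0-6hpi against MII, 8% and 67% for KO against control and 34% and 85% for 10 against 100 embryos. It called 9, 7 and 4 unchanged genes there. Summaries and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.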

Results

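Messenger RNA of mouse embryos produced by in vitro fertilisation was profiled by SLAM-seq, in which 4-thiouridine (4SU) enters newly made RNA and is later read out by alkylation. MII oocytes and embryos in 9 labelling windows, named by hours post insemination (hpi), gave 30 libraries, 3 per group. A second set of 11 libraries carried Klf17 genotype labels (3 controls, 3 KO, 3 maternal KO and 2 paternal KO, here mKO and pKO). Another set compared 10, 40 and 100 embryos per library, with 2 libraries each. Total gene counts per library ran from 7395193 to 13301570, 14080264 to 23018252 and 5144899 to 11589165 in the 3 sets. Replicates correlated across genes at r = 0.951 to 0.985, 0.875 to 0.947 and 0.906 to 0.972, and no pair agreed within sampling noise (smallest chi-square per degree of freedom 4.39, 21.6 and 11.03). Whether the counts hold all reads or only reads with T-to-C conversions is not stated in the sources used here, so levels may include RNA made before labelling. Values in CPM are means ± SD over the libraries of a group (n = 3 unless given), and in each step the earlier group comes first. Counts marked listwise are adjusted over the members of the list alone, and the adjusted p marked estimated is camera's with an estimated correlation between genes.

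Klf17, the Kruppel-like factor whose alleles the genotype labels name, measured 724 ± 62.6 CPM in MII oocytes and 812 ± 168 CPM at 0-6hpi (log2 fold change 0.17, SE 0.26, adjusted p = 0.723). It was at 565 ± 14.9 CPM at 6-12hpi (log2 fold change -0.52, SE 0.26, adjusted p = 0.289) and 621 ± 72.1 CPM at 12-18hpi (log2 fold change 0.14, SE 0.26, adjusted p = 0.811). It fell to 362 ± 52.9 CPM at 18-24hpi (log2 fold change -0.78, SE 0.26, adjusted p = 0.0231), a call lost under total count scaling (adjusted p = 0.0659) and without 12-18hpi replicate 1, 2 or 3 or 18-24hpi replicate 2 or 3 (adjusted p up to 0.134). Levels of 326 ± 48.03 CPM at 24-30hpi (log2 fold change -0.15, SE 0.26, adjusted p = 0.67) and 440.4 ± 65.4 CPM at 30-36hpi (log2 fold change 0.43, SE 0.26, adjusted p = 0.17) followed. Klf17 fell to 269.5 ± 70.2 CPM at 48-54hpi (log2 fold change -0.71, SE 0.26, adjusted p = 0.0212), which was not called without 30-36hpi replicate 3 (adjusted p = 0.0915), then to 15.8 ± 6.29 CPM at 70-76hpi (log2 fold change -4.08, SE 0.30, adjusted p = 8.63e-11) and to 4.14 ± 3.27 CPM at 90-96hpi (log2 fold change -1.94, SE 0.35, adjusted p = 9.4e-05).

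**Figure D1:**
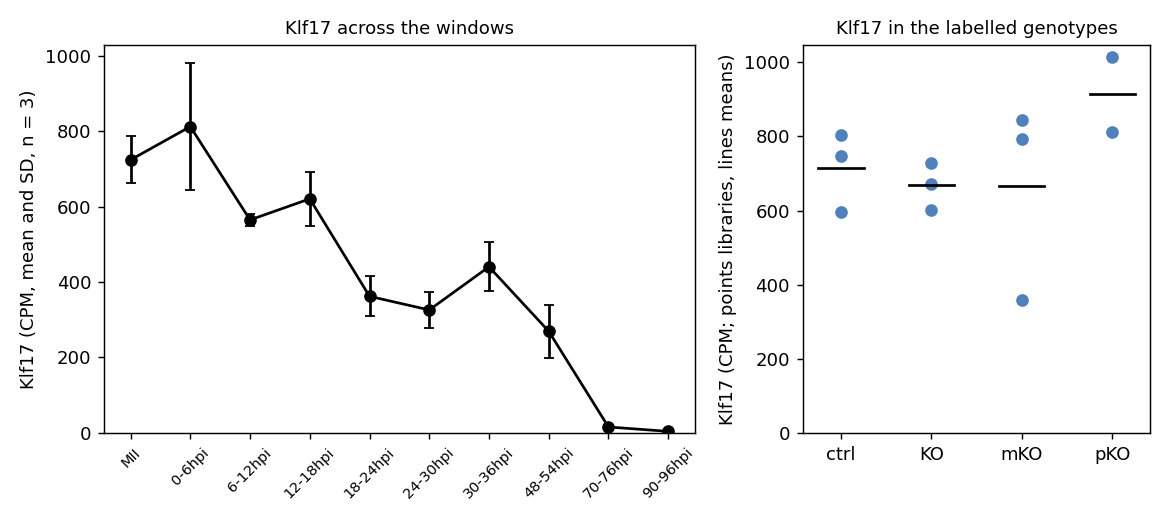
Klf17 in CPM across MII oocytes and the 9 labelling windows (left, mean and SD of 3 libraries) and in each library of the 4 genotype labels (right, points for libraries and lines for means). The mean fell from 270 CPM at 48-54hpi to 15.8 CPM at 70-76hpi, and the KO libraries lie between 603 and 728 CPM, inside the control range of 596 to 805 CPM.

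The steps between consecutive windows ask when polyadenylated RNA levels change around activation of the embryonic genome. From MII to 0-6hpi, 2097 of 16234 genes rose and 1344 fell. AC160063.1 rose from 1.61 ± 1.38 to 27.6 ± 2.46 CPM (log2 fold change 4.10, SE 0.42, adjusted p = 2.96e-09). Car9, a carbonic anhydrase, rose from 4.83 ± 0.289 to 82.7 ± 14.3, Derl3, an endoplasmic reticulum degradation factor, from 2.77 ± 0.8602 to 46.7 ± 5.44 and Samd10 from 3.77 ± 1.81 to 63.3 ± 11.3 CPM. Nfkbiz fell from 95.7 ± 4.68 to 11.8 ± 0.529 CPM (log2 fold change -3.02, SE 0.36, adjusted p = 7.4e-08). Mos, the kinase that maintains metaphase arrest in eggs, fell from 928 ± 99.7 to 187 ± 20.5, Efna1, an ephrin, from 128 ± 20.1 to 33.2 ± 10.2 and Furin, a proprotein convertase, from 49.9 ± 10.2 to 13.3 ± 2.37 CPM. 23 of 51 oxidative phosphorylation genes rose and 4 fell (26 and 5 listwise, camera upward adjusted p = 5.62e-06, 0.309 estimated). Ndufa8, a complex I subunit, rose from 6.21 ± 2.15 to 31.8 ± 3.23 CPM and Cox6a1, a cytochrome c oxidase subunit, from 15.8 ± 3.56 to 54.5 ± 8.77. 7 of 17 glycolysis genes rose and 0 fell (8 and 1 listwise, camera upward adjusted p = 0.0125, 0.382 estimated). Tpi1, triosephosphate isomerase, rose from 6.44 ± 3.75 to 38.6 ± 9.82 CPM and Pkm, a pyruvate kinase, from 37.3 ± 2.57 to 90.8 ± 10.1. 25 of 78 cytosolic ribosomal proteins rose and 12 fell (29 and 13 listwise, camera upward adjusted p = 0.0448, 0.797 estimated). 0 of 20 trophectoderm genes rose and 3 fell (0 and 3 listwise, camera downward adjusted p = 0.0412, 0.469 estimated). Gata3, a trophectoderm transcription factor, fell from 147 ± 10.5 to 85.9 ± 10.4 CPM and Fgfr2, a fibroblast growth factor receptor, from 82.5 ± 4.68 to 52.6 ± 3.697. The call of Fgfr2 was lost under total count scaling (adjusted p = 0.121) and without MII replicate 1 or 3 or 0-6hpi replicate 1, 2 or 3 (adjusted p up to 0.113). With DESeq2 size factors the ribosomal and trophectoderm lists were not called (adjusted p = 0.169 and 0.0653). Rises made up 60.9% of the calls, against 49.4% with DESeq2 size factors, 78.3% with total count scaling and 49.1% in a fit of these 6 libraries alone.

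**Figure D2:**
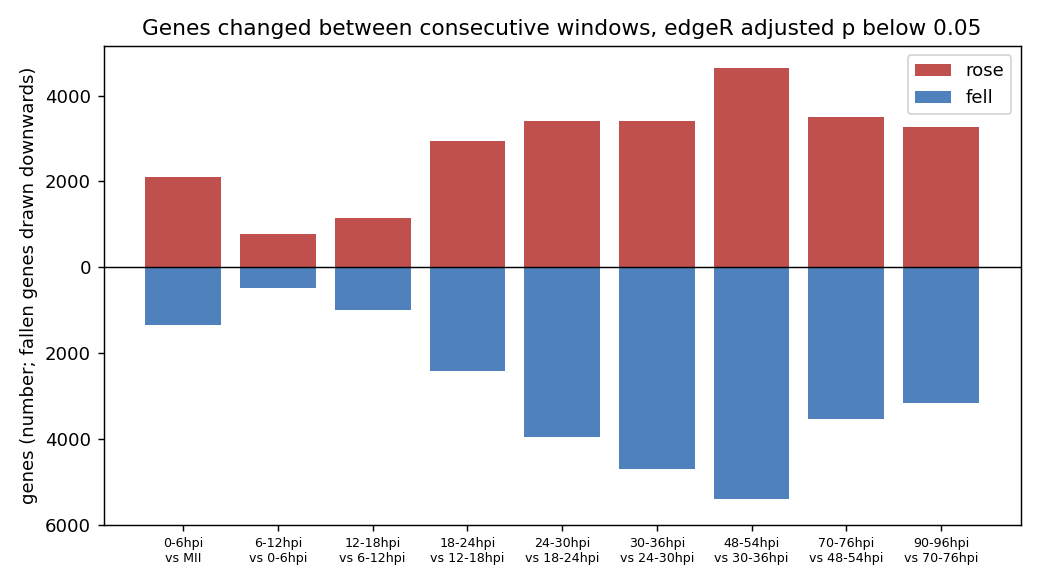
Genes that rose (upward) and fell (downward) at each step between groups, by edgeR at an adjusted p below 0.05. The smallest step is 6-12hpi against 0-6hpi, with 768 rises and 475 falls, and the largest is 48-54hpi against 30-36hpi, with 4653 rises and 5411 falls.

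From 0-6hpi to 6-12hpi, 768 genes rose and 475 fell. Igfbp7 rose from 4.69 ± 1.39 to 20.1 ± 2.14 CPM (log2 fold change 2.09, SE 0.36, adjusted p = 0.00011). Fam162a rose from 8.53 ± 1.57 to 33.6 ± 2.698, Psmb7 from 7.67 ± 0.345 to 28.2 ± 4.697 and Eif3m from 20.6 ± 3.85 to 73.5 ± 1.67 CPM. Efna1 fell from 33.2 ± 10.2 to 5.03 ± 1.08 CPM (log2 fold change -2.72, SE 0.27, adjusted p = 5.25e-09). Astl, the egg protease ovastacin, fell from 152 ± 23.2 to 24.8 ± 7.06 and Med20 from 111 ± 13.2 to 18.4 ± 2.97 CPM. 5 of 29 2-cell-stage genes rose and 0 fell (6 and 0 listwise, camera upward adjusted p = 0.00106, 0.468 estimated). Arg2, the mitochondrial arginase, rose from 167 ± 12.8 to 444 ± 12.1 CPM and Sp110 from 351 ± 32.6 to 494 ± 23.5. The call of Sp110 was lost without 0-6hpi replicate 2 or 3 or 6-12hpi replicate 1, 2 or 3 (adjusted p up to 0.231). 35 of 78 cytosolic ribosomal proteins rose and 1 fell (46 and 2 listwise, camera upward adjusted p = 2.21e-16, 0.279 estimated). Rps24 rose from 37.7 ± 3.81 to 81.5 ± 3.49 CPM and Rps6 from 23.2 ± 1.55 to 52.7 ± 3.19. 8 of 32 proteasome genes rose and 1 fell (10 and 3 listwise, camera upward adjusted p = 0.02, 0.678 estimated). Psmb7 rose from 7.67 ± 0.345 to 28.2 ± 4.697 CPM and Psma6 from 41.8 ± 7.98 to 78.97 ± 4.71. 9 of 35 translation factor genes rose and 0 fell (10 and 3 listwise, camera upward adjusted p = 0.00142, 0.468 estimated). Eif3m rose from 20.6 ± 3.85 to 73.5 ± 1.67 CPM and Eef1e1 from 75.1 ± 2.78 to 174 ± 12.03. 9 of 51 oxidative phosphorylation genes rose and 1 fell (16 and 1 listwise, camera upward adjusted p = 0.000666, 0.469 estimated). Cox4i1 rose from 30.8 ± 4.36 to 56.5 ± 3.18 CPM and Sdhd, a succinate dehydrogenase subunit, from 26.96 ± 0.919 to 65.6 ± 2.95. The count of 1243 changed genes became 3577 in a fit of these 6 libraries alone (51.8% rises, against 61.8%), 739 without 0-6hpi replicate 3 and 820 without 6-12hpi replicate 1.

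From 6-12hpi to 12-18hpi, 1154 genes rose and 989 fell. Zfp352 rose from 3.83 ± 0.897 to 96.7 ± 21.2 CPM (log2 fold change 4.65, SE 0.60, adjusted p = 1.31e-05). Zscan4c rose from 1.99 ± 1.23 to 30.2 ± 11.997, Zscan4d from 6.46 ± 0.694 to 73.98 ± 22.7 and Usp17lc from 3.12 ± 1.18 to 24.5 ± 2.91 CPM. The call of Usp17lc was lost without 6-12hpi replicate 1, 2 or 3 or 12-18hpi replicate 2 or 3 (adjusted p up to 0.1). Gnl2, a nucleolar GTPase, fell from 231 ± 7.91 to 28.8 ± 1.32 CPM (log2 fold change -3.00, SE 0.13, adjusted p = 3.45e-18). Ercc5, a DNA repair nuclease, fell from 48.1 ± 0.574 to 7.33 ± 0.497, Txnip, a thioredoxin-interacting protein, from 413 ± 29.1 to 67.2 ± 17.7 and Rbm28 from 128 ± 6.499 to 23.8 ± 6.68 CPM. 24 of 29 2-cell-stage genes rose and 1 fell (25 and 2 listwise, camera upward adjusted p = 4.16e-11, 0.0988 estimated). Sp110 fell from 494 ± 23.5 to 242 ± 39.3 CPM and Zfp352 rose from 3.83 ± 0.897 to 96.7 ± 21.2 CPM. Zscan4, Usp17l, Tdpoz and Obox genes belong to families of near-identical copies, so their single values are uncertain. 1 of 30 oocyte and maternal-effect genes rose and 4 fell (1 and 4 listwise, camera downward adjusted p = 0.0215, 0.678 estimated). Zp3, a zona pellucida glycoprotein, fell from 205 ± 10.4 to 85.2 ± 10.97 CPM and Padi6, a protein of the cytoplasmic lattices, from 448 ± 15.8 to 224 ± 35.1. 4 of 20 embryonic transcription factors rose and 1 fell (7 and 1 listwise, camera upward adjusted p = 0.0461, 0.322 estimated). Nfya, a subunit of the CCAAT-binding factor, fell from 127 ± 19.05 to 67.8 ± 5.703 CPM and Yap1, the Hippo pathway coactivator, measured 67.4 ± 4.72 and 89.4 ± 4.33 CPM (adjusted p = 0.0955). 5 of 45 ribosome biogenesis genes rose and 21 fell (6 and 21 listwise, camera downward adjusted p = 6.73e-18, 0.0108 estimated). Gnl2 fell from 231 ± 7.91 to 28.8 ± 1.32 CPM and Nop14 from 70.1 ± 2.95 to 14.6 ± 2.97. 10 of 78 cytosolic ribosomal proteins rose and 23 fell (15 and 28 listwise, camera downward adjusted p = 0.00435, 0.748 estimated). Rpl13 fell from 76.2 ± 7.57 to 23.3 ± 5.22 CPM. 3 of 32 proteasome genes rose and 12 fell (5 and 12 listwise, camera downward adjusted p = 0.000993, 0.528 estimated). Psmb7 fell from 28.2 ± 4.697 to 10.6 ± 0.223 CPM and Psma7 from 927 ± 7.34 to 436 ± 10.1. 6 of 35 translation factor genes rose and 9 fell (7 and 10 listwise, camera downward adjusted p = 0.00655, 0.5 estimated). Eif3c fell from 109 ± 7.28 to 25.7 ± 4.89 CPM and Eif3m from 73.5 ± 1.67 to 20.9 ± 3.63. 5 of 20 p53 target genes rose and 0 fell (5 and 0 listwise, camera upward adjusted p = 0.00683, 0.071 estimated). Plk2, a polo-like kinase, rose from 6.19 ± 1.86 to 21.7 ± 8.34 CPM and Trp53inp1, a p53-induced nuclear protein, measured 182 ± 18.8 and 231 ± 13.7 CPM (adjusted p = 0.223). The count of 2143 changed genes became 3628 in a fit of these 6 libraries alone, 1402 without 6-12hpi replicate 2, 1359 without 6-12hpi replicate 3 and 1201 without 12-18hpi replicate 2. Rises made up 53.8% of the calls, 46.9% in that fit and 43.5% with total count scaling, where the embryonic transcription factors were not called (adjusted p = 0.0568).

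Against MII oocytes, 4537 genes had risen and 2589 had fallen by 12-18hpi (63.7% rises, and 51.0% in a fit of these 6 libraries alone). 25 of 29 2-cell-stage genes rose and 1 fell (26 and 1 listwise, camera upward adjusted p = 3.02e-06, 0.256 estimated). Arg2 rose from 31.4 ± 7.19 to 329 ± 36.4 CPM and Tcstv3 from 12.6 ± 3.41 to 77.1 ± 9.78. 38 of 51 oxidative phosphorylation genes rose and 2 fell (39 and 2 listwise, camera upward adjusted p = 4.91e-06, 0.304 estimated). Ndufa8 rose from 6.21 ± 2.15 to 53.5 ± 1.76 CPM and Cox6a1 from 15.8 ± 3.56 to 78.5 ± 7.18. 9 of 17 glycolysis genes rose and 0 fell (11 and 0 listwise, camera upward adjusted p = 0.00338, 0.304 estimated). Pkm rose from 37.3 ± 2.57 to 177 ± 13.6 CPM and Gpi1 from 5.87 ± 1.75 to 36.9 ± 7.75. 51 of 78 cytosolic ribosomal proteins rose and 7 fell (51 and 7 listwise, camera upward adjusted p = 0.00178, 0.709 estimated). Rpl13 fell from 108 ± 16.2 to 23.3 ± 5.22 CPM. 11 of 45 ribosome biogenesis genes rose and 21 fell (12 and 21 listwise, camera downward adjusted p = 0.000344, 0.287 estimated). Gnl2 fell from 259 ± 8.87 to 28.8 ± 1.32 CPM and Nop58 from 309.6 ± 17.000 to 55.98 ± 9.62. The median log2 fold change of ribosome biogenesis was -0.07, and 0.04 with total count scaling.

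From 12-18hpi to 18-24hpi, 2946 genes rose and 2415 fell (55.0% rises, and 64.3% with total count scaling). Tacr3, a tachykinin receptor, rose from 0.529 ± 0.465 to 43.3 ± 10.3 CPM (log2 fold change 6.29, SE 0.73, adjusted p = 6.6e-08). Zfp599 rose from 0.556 ± 0.676 to 39.6 ± 16.1, Tdpoz1 from 1.58 ± 1.18 to 109 ± 43.6 and Ccnjl from 0.386 ± 0.129 to 23.2 ± 3.27 CPM. Apeh fell from 20.5 ± 5.301 to 1.89 ± 0.802 CPM (log2 fold change -3.44, SE 0.37, adjusted p = 1.77e-09). Nelfcd fell from 63.2 ± 1.01 to 7.43 ± 0.897, Nup93, a nuclear pore protein, from 279 ± 46.1 to 34.001 ± 3.39 and Speer4f2 from 37.4 ± 10.6 to 4.93 ± 4.304 CPM. 24 of 29 2-cell-stage genes rose and 2 fell (24 and 2 listwise, camera upward adjusted p = 1.01e-05, 0.275 estimated). AF067063 rose from 3.45 ± 0.262 to 61.6 ± 9.75 CPM and Tdpoz1 from 1.58 ± 1.18 to 109 ± 43.6. 0 of 30 oocyte and maternal-effect genes rose and 12 fell (0 and 13 listwise, camera downward adjusted p = 0.000261, 0.5 estimated). Tle6, part of the subcortical maternal complex, fell from 329 ± 59.4 to 74.1 ± 16.4 CPM and Padi6 from 224 ± 35.1 to 69.3 ± 4.95. 10 of 20 embryonic transcription factors rose and 3 fell (11 and 3 listwise, camera upward adjusted p = 0.0135, 0.224 estimated). Dppa4 rose from 12.6 ± 0.119 to 55.2 ± 15.1 CPM and Gabpa, an ETS factor, from 9.77 ± 3.87 to 159 ± 40.03. 9 of 19 pluripotency and inner cell mass genes rose and 2 fell (9 and 2 listwise, camera upward adjusted p = 0.0068, 0.119 estimated). Tbx3 rose from 3.39 ± 1.73 to 20.9 ± 0.901 CPM and Zfp42 from 1.92 ± 1.61 to 22.3 ± 5.38. 64 of 78 cytosolic ribosomal proteins rose and 1 fell (66 and 1 listwise, camera upward adjusted p = 1.92e-28, 0.119 estimated). Rps26 rose from 30.8 ± 4.15 to 166 ± 14.9 CPM and Rpl23a from 6.09 ± 1.77 to 45.3 ± 2.93. 4 of 32 proteasome genes rose and 19 fell (5 and 21 listwise, camera downward adjusted p = 7.52e-07, 0.369 estimated). Psmc5 fell from 168 ± 16.9 to 29.4 ± 4.897 CPM and Psma7 from 436 ± 10.1 to 104 ± 22.9. 7 of 20 p53 target genes rose and 3 fell (7 and 3 listwise, camera upward adjusted p = 0.00788, 0.0622 estimated). Cdkn1a, a cyclin-dependent kinase inhibitor, rose from 8.26 ± 1.06 to 61.8 ± 3.62 CPM and Ddit4l from 9.16 ± 4.66 to 100.1 ± 21.3. 8 of 20 unfolded protein and heat shock genes rose and 2 fell (8 and 2 listwise, camera upward adjusted p = 0.0358, 0.223 estimated). Dnajb9, an endoplasmic reticulum co-chaperone, rose from 80.9 ± 9.51 to 542 ± 70.2 CPM and Hsp90aa1, a cytosolic chaperone, fell from 772 ± 122 to 374 ± 19.5 CPM. 7 of 30 cell cycle genes rose and 12 fell (7 and 12 listwise, camera downward adjusted p = 0.0308, 0.468 estimated). Ccne1, a cyclin, rose from 12.1 ± 0.722 to 116 ± 11.8 CPM and Bub1b, a spindle checkpoint kinase, fell from 147 ± 14.6 to 34.2 ± 4.81 CPM. The cell cycle list was not called with DESeq2 size factors (adjusted p = 0.0511) or total count scaling (adjusted p = 0.0523).

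From 18-24hpi to 24-30hpi, 3412 genes rose and 3953 fell. Uqcc3 rose from 2.74 ± 0.472 to 45.4 ± 1.55 CPM (log2 fold change 4.04, SE 0.29, adjusted p = 1.89e-13). Pdxk rose from 14.5 ± 4.601 to 191 ± 18.7, Trp53bp2 from 1.61 ± 0.902 to 21.03 ± 6.89 and Yif1b from 2.78 ± 1.27 to 35.8 ± 6.24 CPM. Zc4h2 fell from 32.7 ± 12.3 to 1.67 ± 1.88 CPM (log2 fold change -4.32, SE 0.47, adjusted p = 3.48e-09). Chac2 fell from 26.9 ± 10.8 to 2.22 ± 0.8404, Slc30a3, a zinc transporter, from 237 ± 50.7 to 22.4 ± 0.882 and Crabp2, a retinoic acid-binding protein, from 347 ± 74.6 to 33.3 ± 2.45 CPM. 0 of 30 oocyte and maternal-effect genes rose and 16 fell (1 and 16 listwise, camera downward adjusted p = 0.00115, 0.528 estimated). Ooep, part of the subcortical maternal complex, fell from 188 ± 39.2 to 42.97 ± 13.2 CPM and Nobox, an oocyte homeobox factor, from 129 ± 18.3 to 26.7 ± 4.001. 10 of 20 embryonic transcription factors rose and 0 fell (10 and 2 listwise, camera upward adjusted p = 0.0243, 0.271 estimated). Dppa4 rose from 55.2 ± 15.1 to 195 ± 10.7 CPM and Yy1 from 40.9 ± 9.24 to 102 ± 3.53. 68 of 78 cytosolic ribosomal proteins rose and 1 fell (69 and 1 listwise, camera upward adjusted p = 6.85e-18, 0.256 estimated). Rpl13 rose from 68.7 ± 2.65 to 205 ± 14.7 CPM and Rpl19 from 42.03 ± 4.44 to 117 ± 11.9. 36 of 45 ribosome biogenesis genes rose and 2 fell (36 and 2 listwise, camera upward adjusted p = 6.51e-19, 0.0108 estimated). Gnl2 rose from 22.97 ± 4.38 to 81.3 ± 8.78 CPM and Nop2 from 15.9 ± 5.41 to 92.9 ± 0.846. 18 of 32 proteasome genes rose and 9 fell (18 and 10 listwise, camera upward adjusted p = 0.00524, 0.593 estimated). Psmb5 rose from 3.696 ± 0.829 to 46.5 ± 3.305 CPM and Psmb6 fell from 239 ± 10.5 to 59.6 ± 8.96 CPM. 19 of 35 translation factor genes rose and 8 fell (19 and 8 listwise, camera upward adjusted p = 0.0129, 0.528 estimated). Eif4a1 fell from 266 ± 12.9 to 82.1 ± 9.14 CPM and Eif3c rose from 37.1 ± 7.98 to 151 ± 8.28 CPM. 10 of 17 glycolysis genes rose and 2 fell (10 and 2 listwise, camera upward adjusted p = 0.0315, 0.469 estimated). Eno1, an enolase, rose from 22.8 ± 5.67 to 84.01 ± 15.4 CPM and Pkm from 102 ± 24.3 to 232 ± 28.1. Rises made up 46.3% of the calls, against 69.0% with total count scaling and 52.3% in a fit of these 6 libraries alone.

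From 24-30hpi to 30-36hpi, 3407 genes rose and 4700 fell (42.0% rises, and 50.8% in a fit of these 6 libraries alone). Hand1, a trophoblast transcription factor, rose from 2.398 ± 1.87 to 38.6 ± 6.08 CPM (log2 fold change 4.02, SE 0.64, adjusted p = 1.85e-05). Isyna1, inositol phosphate synthase, rose from 11.3 ± 6.31 to 153 ± 7.63, Fez2 from 2.92 ± 0.415 to 39.2 ± 8.46 and Nipal1 from 22.2 ± 8.91 to 256 ± 40.6 CPM. AC131117.1 fell from 45.3 ± 10.7 to 3.09 ± 0.495 CPM (log2 fold change -3.88, SE 0.36, adjusted p = 1.43e-10). Iglc3 fell from 25.03 ± 3.33 to 1.71 ± 0.398, Grm4 from 42.6 ± 11.1 to 3.19 ± 0.229 and Hes1, a Notch target, from 66.2 ± 24.7 to 5.01 ± 1.45 CPM. 2 of 29 2-cell-stage genes rose and 20 fell (2 and 20 listwise, camera downward adjusted p = 0.0186, 0.558 estimated). Tcstv1 fell from 100.5 ± 5.96 to 17.6 ± 3.04 CPM and Tcstv3 from 70.4 ± 4.15 to 15.4 ± 6.25. 9 of 20 embryonic transcription factors rose and 2 fell (10 and 2 listwise, camera upward adjusted p = 0.00435, 0.148 estimated). Dppa2 rose from 205 ± 23.6 to 983 ± 40.6 CPM and Tead4, a trophectoderm transcription factor, from 9.17 ± 1.14 to 50.7 ± 13.6. 74 of 78 cytosolic ribosomal proteins rose and 0 fell (75 and 0 listwise, camera upward adjusted p = 8.84e-26, 0.147 estimated). Rpl5 rose from 90.8 ± 6.58 to 251 ± 21.5 CPM and Rpl10 from 208 ± 11.9 to 568 ± 55.5. 40 of 45 ribosome biogenesis genes rose and 0 fell (41 and 0 listwise, camera upward adjusted p = 3.91e-19, 0.0108 estimated). Wdr43 rose from 193 ± 19.2 to 482 ± 3.72 CPM and Noc4l from 61.2 ± 11.3 to 191 ± 19.3. 28 of 46 spliceosome genes rose and 5 fell (30 and 5 listwise, camera upward adjusted p = 7.06e-06, 0.0622 estimated). Eftud2, a spliceosomal GTPase, rose from 4.99 ± 0.417 to 29.95 ± 3.32 CPM and Snrnp200 from 23.6 ± 6.93 to 91.6 ± 21.9. 31 of 32 proteasome genes rose and 0 fell (31 and 0 listwise, camera upward adjusted p = 3.66e-17, 0.0988 estimated). Adrm1 rose from 67.9 ± 8.36 to 243 ± 20.2 CPM and Psma6 from 103 ± 9.65 to 337 ± 7.58. 29 of 35 translation factor genes rose and 3 fell (29 and 3 listwise, camera upward adjusted p = 1.3e-13, 0.06 estimated). Eif3d rose from 21.6 ± 1.83 to 87.2 ± 14.6 CPM and Eif3a from 191 ± 4.11 to 659 ± 155. 29 of 51 oxidative phosphorylation genes rose and 9 fell (29 and 9 listwise, camera upward adjusted p = 0.00561, 0.528 estimated). Atp5a1, an ATP synthase subunit, rose from 221 ± 5.58 to 503 ± 68.2 CPM and Uqcrc2 from 34.99 ± 4.36 to 79.8 ± 8.56. 14 of 30 cell cycle genes rose and 5 fell (14 and 5 listwise, camera upward adjusted p = 0.0215, 0.413 estimated). Cdc20, an activator of the anaphase-promoting complex, rose from 264 ± 27.3 to 856 ± 107 CPM and Plk1, a mitotic kinase, from 119 ± 24.6 to 295 ± 28.5.

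**Figure D3:**
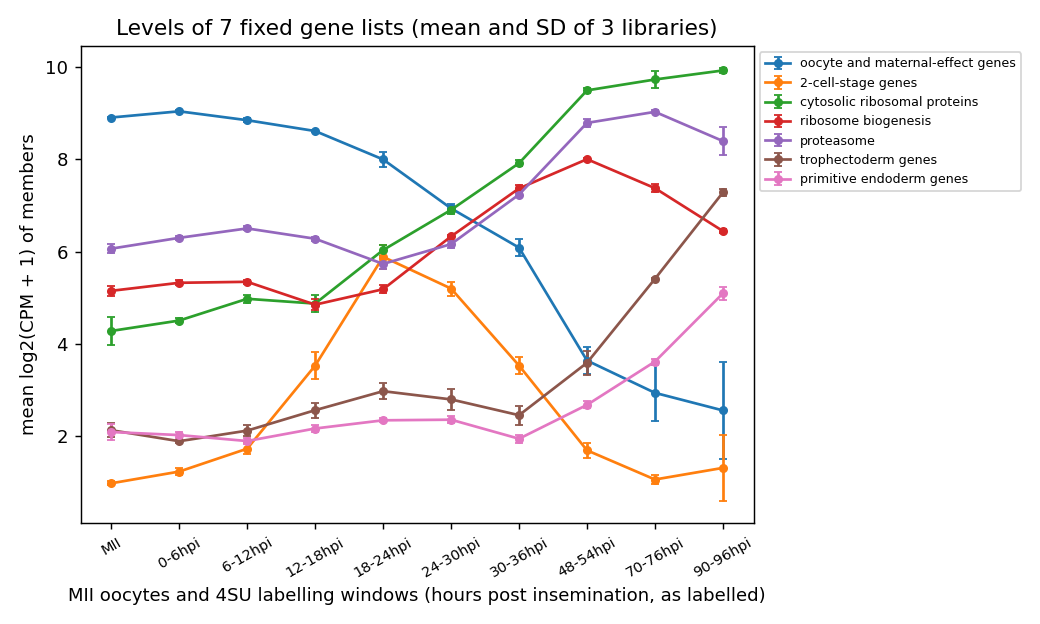
Mean log2(CPM + 1) of the measured members of 7 fixed gene lists in MII oocytes and each labelling window (mean and SD of 3 libraries). The 2-cell-stage genes peak at 18-24hpi and the trophectoderm and primitive endoderm genes are highest at 90-96hpi.

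From 30-36hpi to 48-54hpi, 4653 genes rose and 5411 fell. Vnn1, a pantetheinase, rose from 0.153 ± 0.0484 to 350.4 ± 121 CPM (log2 fold change 11.03, SE 0.67, adjusted p = 3.97e-12). Cldn4, a tight junction claudin, rose from 0.102 ± 0.101 to 37.2 ± 3.84 and Ly6a from 0.235 ± 0.407 to 73.3 ± 16.1 CPM. Rundc3b fell from 34.2 ± 11.4 to 0.149 ± 0.258 CPM (log2 fold change -7.83, SE 0.46, adjusted p = 1.35e-16). Cobl fell from 20.6 ± 5.86 to 0.0971 ± 0.0938, Adarb2 from 53.01 ± 3.97 to 0.426 ± 0.414 and Gpm6a from 44.9 ± 8.13 to 0.465 ± 0.347 CPM. 2 of 30 oocyte and maternal-effect genes rose and 27 fell (2 and 27 listwise, camera downward adjusted p = 4.08e-05, 0.469 estimated). Khdc3, part of the subcortical maternal complex, rose from 14.7 ± 1.07 to 214 ± 32.7 CPM and Zp2, a zona pellucida glycoprotein, fell from 33.95 ± 8.23 to 3.805 ± 2.39 CPM. 1 of 29 2-cell-stage genes rose and 22 fell (1 and 22 listwise, camera downward adjusted p = 0.0144, 0.528 estimated). Arg2 fell from 96.7 ± 27.4 to 26.3 ± 3.41 CPM and AF067063 from 148 ± 40.5 to 33.6 ± 4.495. 13 of 19 pluripotency and inner cell mass genes rose and 4 fell (13 and 4 listwise, camera upward adjusted p = 0.0276, 0.216 estimated). Tdgf1, a Nodal co-receptor, rose from 8.33 ± 4.598 to 349 ± 62.8 CPM and Pou5f1, a pluripotency factor, from 3.68 ± 1.01 to 22.3 ± 3.75. 78 of 78 cytosolic ribosomal proteins rose and 0 fell (78 and 0 listwise, camera upward adjusted p = 1.96e-29, 0.119 estimated). Rpl5 rose from 251 ± 21.5 to 1325 ± 102 CPM and Rpl17 from 155 ± 10.4 to 608 ± 22.3. 30 of 45 ribosome biogenesis genes rose and 2 fell (30 and 2 listwise, camera upward adjusted p = 0.000122, 0.256 estimated). Npm1, nucleophosmin, rose from 1705 ± 172 to 4915 ± 365 CPM and Gnl2 from 157 ± 8.28 to 488 ± 37.9. 34 of 46 spliceosome genes rose and 0 fell (34 and 0 listwise, camera upward adjusted p = 4.85e-09, 0.0158 estimated). Srsf3, a splicing factor, rose from 161 ± 32.5 to 1224 ± 70.3 CPM and Eftud2 from 29.95 ± 3.32 to 184 ± 7.61. 32 of 32 proteasome genes rose and 0 fell (32 and 0 listwise, camera upward adjusted p = 6.3e-17, 0.106 estimated). Psma7 rose from 143 ± 29.2 to 681 ± 63.1 CPM and Psmc5 from 120.4 ± 7.497 to 544 ± 42.7. 34 of 35 translation factor genes rose and 0 fell (34 and 0 listwise, camera upward adjusted p = 1.01e-14, 0.0461 estimated). Eef1b2 rose from 138 ± 23.03 to 722 ± 72.1 CPM and Eif2s2 from 804 ± 55.8 to 3245 ± 219.8. 46 of 51 oxidative phosphorylation genes rose and 3 fell (46 and 3 listwise, camera upward adjusted p = 2.78e-13, 0.0922 estimated). Sdha rose from 17.1 ± 2.502 to 104 ± 14.6 CPM and Ndufa10 from 23.5 ± 1.95 to 179 ± 10.4. 11 of 20 p53 target genes rose and 5 fell (11 and 5 listwise, camera upward adjusted p = 0.0306, 0.153 estimated). Perp, an apoptosis-associated membrane protein, rose from 1.14 ± 0.831 to 99.4 ± 8.51 CPM and Rrm2b, a ribonucleotide reductase subunit, fell from 179 ± 5.64 to 15.3 ± 2.36 CPM. 21 of 30 cell cycle genes rose and 5 fell (21 and 5 listwise, camera upward adjusted p = 0.000249, 0.153 estimated). Ccnb2, a mitotic cyclin, rose from 40.4 ± 0.565 to 208 ± 9.03 CPM and Mcm5, a replicative helicase subunit, from 19.2 ± 2.49 to 155 ± 15.3. With total count scaling rises made up 32.5% of the calls, against 46.2%, and the 2-cell-stage list was not called (adjusted p = 0.0590).

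From 48-54hpi to 70-76hpi, 3511 genes rose and 3540 fell. Hal, histidine ammonia-lyase, rose from 0.0744 ± 0.129 to 22.8 ± 2.87 CPM (adjusted p = 1.18e-08, with 2 reads in the lower group and no fold given). Tpp1, a lysosomal peptidase, rose from 0.268 ± 0.241 to 76.4 ± 17.2, Hspb8 from 0.364 ± 0.458 to 94.96 ± 14.4 and Oxt, the oxytocin precursor, from 0.329 ± 0.491 to 43.2 ± 11.1 CPM. Aqp11, an aquaporin, fell from 142 ± 19.1 to 3.05 ± 0.973 CPM (log2 fold change -5.54, SE 0.33, adjusted p = 9.41e-16). Obox8 fell from 254 ± 61.6 to 6.54 ± 9.15, Acsl4, an acyl-CoA synthetase, from 431 ± 31.8 to 12.2 ± 2.73 and Sardh from 22.7 ± 0.681 to 0.746 ± 0.1096 CPM. 16 of 20 trophectoderm genes rose and 1 fell (16 and 1 listwise, camera upward adjusted p = 2.44e-07, 0.0461 estimated). Gata3 rose from 14.8 ± 4.27 to 239.5 ± 36.3 CPM and Ptges from 3.94 ± 2.67 to 173 ± 11.3. 11 of 20 primitive endoderm genes rose and 1 fell (11 and 1 listwise, camera upward adjusted p = 0.0068, 0.0622 estimated). Gata4, an endoderm transcription factor, fell from 48.97 ± 9.35 to 1.97 ± 0.0899 CPM and Lamb1, a laminin chain, rose from 13.7 ± 4.17 to 69.4 ± 9.002 CPM. 3 of 30 oocyte and maternal-effect genes rose and 14 fell (4 and 14 listwise, camera downward adjusted p = 0.0154, 0.655 estimated). Zp3 fell from 85.9 ± 9.67 to 11.9 ± 2.32 CPM and Ooep rose from 2.07 ± 1.02 to 20.4 ± 2.51 CPM. 1 of 20 embryonic transcription factors rose and 10 fell (1 and 11 listwise, camera downward adjusted p = 0.00685, 0.17 estimated). Dppa2 fell from 2308 ± 49.9 to 1032 ± 127 CPM and Nr5a2 from 169.6 ± 11.3 to 57.9 ± 10.7. 29 of 78 cytosolic ribosomal proteins rose and 0 fell (24 and 0 listwise, camera upward adjusted p = 0.0194, 0.797 estimated). Rpl31 rose from 368 ± 16.2 to 560.4 ± 84.1 CPM and Rpl41 from 484 ± 17.4 to 729 ± 87.7. 2 of 45 ribosome biogenesis genes rose and 30 fell (2 and 32 listwise, camera downward adjusted p = 5.55e-07, 0.119 estimated). Wdr43 fell from 1119 ± 69.2 to 313 ± 51.1 CPM and Heatr1 from 447 ± 15.5 to 98.2 ± 10.1. 3 of 35 translation factor genes rose and 17 fell (4 and 17 listwise, camera downward adjusted p = 0.0154, 0.528 estimated). Eif4e fell from 2347 ± 101 to 513 ± 42.9 CPM and Eif5b from 688 ± 86.3 to 248 ± 53.1. 40 of 51 oxidative phosphorylation genes rose and 0 fell (42 and 1 listwise, camera upward adjusted p = 5.39e-08, 0.224 estimated). Ndufab1 rose from 66.6 ± 5.31 to 159 ± 21.8 CPM and Sdhc from 13.8 ± 0.348 to 56.1 ± 6.54. 14 of 20 p53 target genes rose and 1 fell (14 and 1 listwise, camera upward adjusted p = 9.35e-07, 0.00782 estimated). Btg2, an antiproliferative factor, rose from 14.4 ± 2.86 to 265 ± 25.5 CPM and Ddit4l from 30.7 ± 1.45 to 151 ± 20.2. 4 of 30 cell cycle genes rose and 20 fell (5 and 20 listwise, camera downward adjusted p = 0.000239, 0.147 estimated). Ccnb1, a mitotic cyclin, fell from 3795 ± 212 to 1042 ± 110.3 CPM and Ccne2 from 107 ± 15.1 to 31.2 ± 1.67. With total count scaling rises made up 61.7% of the calls, against 49.8%, and the translation list was not called (adjusted p = 0.112).

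From 70-76hpi to 90-96hpi, 3256 genes rose and 3166 fell (50.7% rises, 48.4% with DESeq2 size factors and 56.7% with total count scaling). Adh1, an alcohol dehydrogenase, rose from 0.742 ± 1.19 to 205 ± 58.97 CPM (log2 fold change 8.13, SE 0.65, adjusted p = 6.3e-11). Gata2, a trophoblast transcription factor, rose from 0.137 ± 0.0649 to 39.6 ± 12.7, Lama1, a laminin chain, from 0.262 ± 0.239 to 47.7 ± 12.5 and Dppa1 from 8.21 ± 2.41 to 678 ± 68.1 CPM. Trim43b fell from 136 ± 51.8 to 2.11 ± 1.62 CPM (log2 fold change -6.02, SE 0.40, adjusted p = 1.43e-11). Cthrc1 fell from 34.6 ± 13.7 to 0.866 ± 0.762, Slc25a41 from 61.7 ± 8.72 to 1.61 ± 0.524 and Stmn3, a stathmin, from 300.0 ± 23.8 to 9.39 ± 4.43 CPM. 15 of 20 trophectoderm genes rose and 2 fell (15 and 2 listwise, camera upward adjusted p = 3.33e-08, 0.0431 estimated). Dppa1 rose from 8.21 ± 2.41 to 678 ± 68.1 CPM and Id2, an inhibitor of helix-loop-helix factors, from 106 ± 25.2 to 1304 ± 120.5. 13 of 20 primitive endoderm genes rose and 1 fell (13 and 2 listwise, camera upward adjusted p = 0.00044, 0.0219 estimated). Sparc, a matrix glycoprotein, rose from 16.1 ± 3.54 to 246 ± 96.97 CPM and Lama1 from 0.262 ± 0.239 to 47.7 ± 12.5. 8 of 15 KLF family genes rose and 1 fell (8 and 1 listwise, camera upward adjusted p = 0.0215, 0.324 estimated). Klf6 rose from 45.1 ± 8.94 to 248 ± 26.8 CPM and Klf5 from 162 ± 18.3 to 455 ± 39.002. 1 of 45 ribosome biogenesis genes rose and 38 fell (1 and 39 listwise, camera downward adjusted p = 1.17e-17, 0.0118 estimated). Wdr43 fell from 313 ± 51.1 to 102 ± 1.99 CPM and Dkc1 from 458 ± 16.3 to 154 ± 22.6. 0 of 32 proteasome genes rose and 23 fell (0 and 23 listwise, camera downward adjusted p = 4.95e-07, 0.324 estimated). Psmd11 fell from 787 ± 44.1 to 331 ± 79.1 CPM and Psmd1 from 601 ± 120.0 to 269 ± 32.6. 2 of 35 translation factor genes rose and 21 fell (2 and 21 listwise, camera downward adjusted p = 5.62e-06, 0.25 estimated). Eif5 fell from 2264 ± 167 to 684 ± 97.7 CPM and Eif6 from 409.8 ± 22.04 to 109 ± 33.3. 32 of 51 oxidative phosphorylation genes rose and 4 fell (33 and 4 listwise, camera upward adjusted p = 9.44e-08, 0.216 estimated). Cox7b rose from 84.8 ± 16.96 to 281 ± 42.3 CPM and Ndufab1 from 159 ± 21.8 to 349.5 ± 11.8. 0 of 20 p53 target genes rose and 12 fell (1 and 12 listwise, camera downward adjusted p = 0.000239, 0.0158 estimated). Mdm2, the ubiquitin ligase of p53, fell from 289 ± 55.04 to 119 ± 29.6 CPM and Plk2 from 296 ± 53.4 to 43.8 ± 8.56. 4 of 30 cell cycle genes rose and 15 fell (4 and 16 listwise, camera downward adjusted p = 0.0106, 0.324 estimated). Ccne1 fell from 248 ± 44.7 to 53.02 ± 13.6 CPM and Ccna2 from 554 ± 93.3 to 249 ± 16.3. Trim43b has near-identical copies, so its value is uncertain.

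The genotype libraries ask what changes when Klf17 is lost from both parents, the mother or the father. Klf17 itself measured 668 ± 62.8 CPM in the libraries labelled KO (673, 603 and 728), 716 ± 108 CPM in the controls (596, 805 and 746), 666 ± 267 CPM in mKO (359, 845 and 794) and 913 ± 144 CPM in pKO (812 and 1015, n = 2). Against the controls its log2 fold change was -0.10 in KO (SE 0.30, adjusted p = 0.869), -0.10 in mKO (SE 0.30, adjusted p = 0.954) and 0.35 in pKO (SE 0.33, adjusted p = 1). The gene-level counts thus give no check of the genotype labels, and the deleted part of the gene is not given in the sources used here. Mitochondrial genes held 5.92 to 11.4% of reads in the libraries labelled KO and 3.23 to 4.18% in the controls.

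In the libraries labelled KO, 304 of 16694 genes were higher than in the controls and 1054 were lower. Each left-out library lowered that count of 1358, to 892, 270 and 188 without control replicate 1, 2 and 3, and to 269, 0 and 586 without KO replicate 1, 2 and 3. It was 0 with the mitochondrial share of reads as a covariate (1424 unadjusted; median absolute log2 fold change of the 1358 genes 1.60 to 1.14, median SE 0.387 to 0.667), 2698 by DESeq2 and 3166 in a fit of these 6 libraries alone. Rises made up 22.4% of the calls, but 31.2% with DESeq2 size factors, 37.3% in that fit of 6 and 42.0% by DESeq2. Atf3, a stress-induced transcription factor, rose from 1.47 ± 0.843 to 30.8 ± 10.7 CPM (log2 fold change 4.38, SE 0.74, adjusted p = 0.00661). Rnase4 rose from 6.97 ± 3.47 to 37.7 ± 21.4, Ahnak from 5.91 ± 1.39 to 31.02 ± 15.1, AC131117.1 from 9.96 ± 6.43 to 50.97 ± 26.3, Gstm1, a glutathione transferase, from 13.3 ± 8.01 to 67.7 ± 20.1 and Gabrq from 9.14 ± 2.88 to 45.5 ± 26.9 CPM. Iqcb1 rose from 4.62 ± 3.18 to 22.5 ± 9.19, Itpripl1 from 16.8 ± 10.3 to 79.6 ± 28.97, Postn, a matrix protein, from 4.34 ± 1.199 to 20.4 ± 6.58, Rap2b from 7.92 ± 1.398 to 36.2 ± 12.6, Dclre1c from 5.08 ± 3.204 to 22.4 ± 7.85 and Sox11, a SOX transcription factor, from 37.7 ± 16.9 to 164 ± 37.6 CPM. Cpn1 fell from 23.7 ± 6.86 to 1.61 ± 1.22 CPM (log2 fold change -3.87, SE 0.69, adjusted p = 0.00772). Stmn3 fell from 154 ± 13.8 to 10.9 ± 3.56, Fbxo6 from 45.9 ± 9.79 to 3.85 ± 1.76, Zfp977 from 27.8 ± 0.8699 to 2.52 ± 1.42, Smyd5 from 104 ± 32.2 to 10.2 ± 3.62 and Gata1, an erythroid transcription factor, from 169.6 ± 24.3 to 16.7 ± 1.44 CPM. Atg7, an autophagy factor, fell from 42.6 ± 7.998 to 4.26 ± 1.66, Tead4 from 37.8 ± 6.13 to 3.801 ± 1.04, Slc5a11 from 36.8 ± 4.24 to 3.75 ± 1.77, Slc39a4, a zinc importer, from 100.0 ± 39.4 to 10.9 ± 3.6998, Impdh1, an IMP dehydrogenase, from 45.8 ± 15.04 to 5.01 ± 1.24 and Sec1 from 50.1 ± 23.4 to 5.86 ± 1.03 CPM. Of these 24 genes, 19, 14 and 14 were still called without control replicate 1, 2 and 3, and 12, 0 and 18 without KO replicate 1, 2 and 3 (highest adjusted p 0.15).

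**Figure D4:**
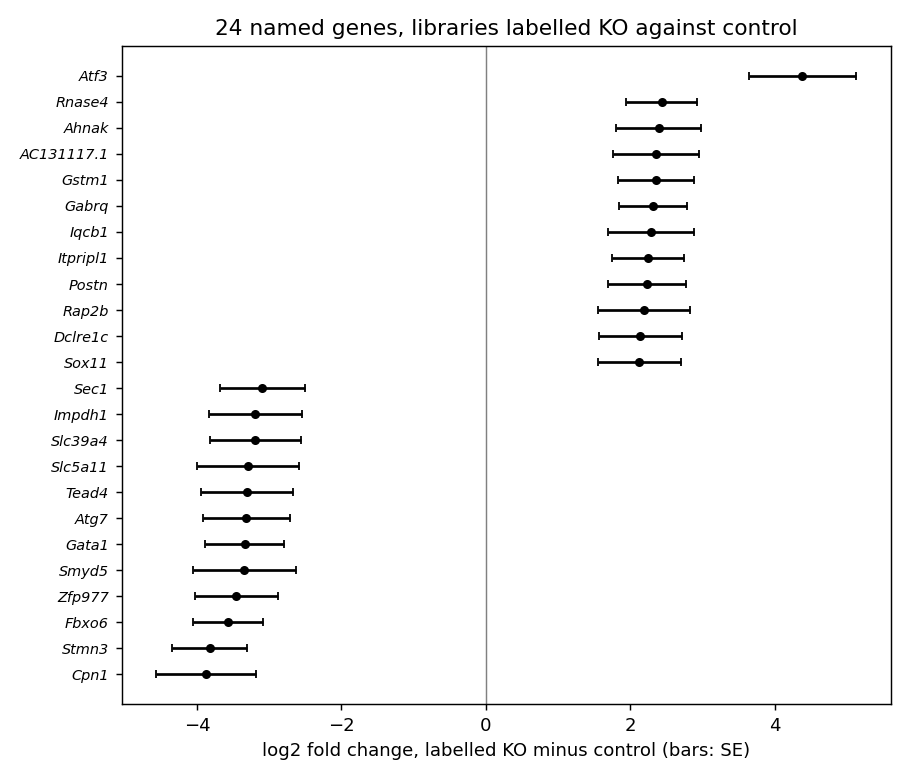
Log2 fold change (libraries labelled KO minus control, points, with SE as bars) of the 12 highest and 12 lowest genes by the naming rule. Atf3 lies highest at 4.38 and Cpn1 lowest at -3.87, and without KO replicate 2 none of the 24 is called.

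Camera called 9 lists between the libraries labelled KO and the controls, 7 of them downward in KO and 2, the trophectoderm and primitive endoderm genes, upward. 0 of 45 ribosome biogenesis genes rose and 25 fell (0 and 38 listwise, camera downward adjusted p = 4.96e-20, 0.509 estimated). Ddx18 fell from 296 ± 34.2 to 80.3 ± 11.5 CPM and Imp3 from 194 ± 3.24 to 57.8 ± 11.9. 0 of 78 cytosolic ribosomal proteins rose and 23 fell (0 and 44 listwise, camera downward adjusted p = 9.03e-16, 0.656 estimated). Rplp0 fell from 2266 ± 22.7 to 959 ± 121 CPM. 0 of 35 translation factor genes rose and 16 fell (0 and 22 listwise, camera downward adjusted p = 5.11e-11, 0.509 estimated). Eif3g fell from 163 ± 27.3 to 42.97 ± 10.5 CPM and Eif4h from 48.4 ± 12.03 to 11.9 ± 4.17. 0 of 32 proteasome genes rose and 11 fell (0 and 21 listwise, camera downward adjusted p = 9.94e-10, 0.509 estimated). Psmd4 fell from 165 ± 28.9 to 39.3 ± 8.64 CPM and Psmd14 from 231 ± 32.7 to 83.9 ± 26.6. 0 of 46 spliceosome genes rose and 7 fell (0 and 10 listwise, camera downward adjusted p = 2.33e-05, 0.509 estimated). Snrpa1 fell from 206 ± 16.1 to 62.6 ± 14.3 CPM and Cdc5l from 137 ± 5.49 to 54.03 ± 17.04. 1 of 51 oxidative phosphorylation genes rose and 5 fell (1 and 7 listwise, camera downward adjusted p = 0.0312, 0.815 estimated). Uqcrc1 fell from 73.5 ± 14.4 to 14.2 ± 6.36 CPM and Ndufb10 from 44.97 ± 6.69 to 16.1 ± 5.11. 1 of 20 embryonic transcription factors rose and 7 fell (2 and 9 listwise, camera downward adjusted p = 0.00869, 0.509 estimated). Tead4 fell from 37.8 ± 6.13 to 3.801 ± 1.04 CPM and Dppa2 from 717 ± 251 to 214 ± 29.7. 1 of 19 trophectoderm genes rose and 1 fell (9 and 1 listwise, camera upward adjusted p = 0.00499, 0.509 estimated). Tfap2c fell from 50.1 ± 6.18 to 17.8 ± 1.95 CPM and Fgfr2 rose from 10.9 ± 0.429 to 30.3 ± 10.6 CPM. 2 of 19 primitive endoderm genes rose and 1 fell (3 and 1 listwise, camera upward adjusted p = 0.0462, 0.671 estimated). Gata4 fell from 100.3 ± 9.57 to 49.2 ± 5.65 CPM and Pdgfra measured 16.8 ± 6.52 and 46.9 ± 6.11 CPM (adjusted p = 0.0547). The primitive endoderm list was not called with DESeq2 size factors (adjusted p = 0.0530) or a replicate block (adjusted p = 0.0521). No list call held with an estimated correlation, and the tests of lists were not repeated with libraries left out. Camera did not call the other 13 lists, though with a replicate block it called the cell cycle genes downward (adjusted p = 0.0436). 1 of 30 oocyte and maternal-effect genes rose and 2 fell (2 and 2 listwise, camera upward adjusted p = 0.121, 0.769 estimated). Zp3 fell from 96.5 ± 15.7 to 39.4 ± 4.09 CPM and Bmp15, an oocyte growth factor, rose from 1104 ± 241 to 2238 ± 217 CPM. 0 of 28 2-cell-stage genes rose and 1 fell (0 and 1 listwise, camera upward adjusted p = 0.42, 0.898 estimated). Sp110 fell from 292 ± 53.2 to 89.9 ± 9.65 CPM and AF067063 measured 197 ± 34.1 and 112 ± 21.8 CPM (adjusted p = 0.0812). 0 of 7 OBOX homeobox genes rose and 2 fell (3 and 2 listwise, camera downward adjusted p = 0.981, 0.995 estimated). Obox8 fell from 262 ± 73.7 to 60.6 ± 10.99 CPM and Obox6 from 969.6 ± 292 to 318 ± 33.9. 2 of 15 KLF family genes rose and 1 fell (2 and 2 listwise, camera upward adjusted p = 0.594, 0.824 estimated). Klf10 rose from 14.3 ± 2.19 to 40.1 ± 10.5 CPM and Klf6 from 7.86 ± 1.83 to 28.99 ± 7.07. 1 of 31 cell cycle genes rose and 8 fell (2 and 10 listwise, camera downward adjusted p = 0.0632, 0.71 estimated). Aurka, a mitotic kinase, fell from 646 ± 48.2 to 257 ± 85.5 CPM and Mcm6 from 414 ± 64.1 to 144 ± 25.5. 1 of 20 unfolded protein and heat shock genes rose and 1 fell (1 and 1 listwise, camera downward adjusted p = 0.899, 0.959 estimated). Atf3 rose from 1.47 ± 0.843 to 30.8 ± 10.7 CPM and Hspa8, a constitutive chaperone, fell from 1601 ± 19.5 to 559.7 ± 27.3 CPM. 0 of 25 chromatin and DNA methylation regulators rose and 3 fell (0 and 5 listwise, camera downward adjusted p = 0.489, 0.797 estimated). Smarca4, a chromatin remodelling ATPase, fell from 67.8 ± 23.9 to 19.4 ± 4.82 CPM and Tet1, a DNA dioxygenase, from 66.05 ± 4.22 to 26.6 ± 11.5. 2 of 22 cholesterol synthesis genes rose and 2 fell (3 and 2 listwise, camera upward adjusted p = 0.848, 0.898 estimated). Msmo1, a sterol oxidase, rose from 39.9 ± 10.7 to 130.1 ± 7.78 CPM and Fdps fell from 35.95 ± 2.04 to 14.7 ± 2.78 CPM. 1 of 19 p53 target genes rose and 1 fell (2 and 2 listwise, camera upward adjusted p = 0.594, 0.795 estimated). Aen fell from 39.1 ± 12.1 to 11.7 ± 3.03 CPM and Sesn2 measured 68.5 ± 30.1 and 22.4 ± 13.4 CPM (adjusted p = 0.0606). 0 of 20 pluripotency and inner cell mass genes rose and 0 fell (2 and 1 listwise, camera upward adjusted p = 0.754, 0.845 estimated). Fgf4 measured 120.3 ± 11.3 and 45.3 ± 18.3 CPM (adjusted p = 0.0664) and Dppa5a measured 293 ± 43.6 and 179 ± 40.5 CPM (adjusted p = 0.148). 0 of 17 glycolysis genes rose and 0 fell (0 and 0 listwise, camera downward adjusted p = 0.962, 0.995 estimated). Gapdh measured 413 ± 101 and 215 ± 67.6 CPM (adjusted p = 0.144) and Pkm measured 522 ± 188 and 260.1 ± 35.6 CPM (adjusted p = 0.238). 0 of 14 cumulus and granulosa cell markers rose and 0 fell (0 and 0 listwise, camera upward adjusted p = 0.962, 0.995 estimated). Amhr2 measured 57.5 ± 10.7 and 20.7 ± 8.54 CPM (adjusted p = 0.0725). 0 of 9 sperm and spermatid markers rose and 0 fell (0 and 0 listwise, camera upward adjusted p = 0.868, 0.93 estimated). Odf2 measured 85.3 ± 8.06 and 117 ± 13.7 CPM (adjusted p = 0.292) and Tsga8 measured 20.1 ± 4.78 and 10.9 ± 4.64 CPM (adjusted p = 0.326). Median, mean and test differed in sign for the OBOX genes (median 0.54, mean -0.01, downward), the unfolded protein genes (-0.36, 0.05, downward), the cumulus markers (-0.08, -0.38, upward) and the cholesterol genes (-0.04, 0.01, upward). Of 30 called genes named for the 22 lists, 25, 12 and 11 were called without control replicate 1, 2 and 3, and 12, 0 and 16 without KO replicate 1, 2 and 3 (highest adjusted p 0.159).

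Between mKO and the controls edgeR called 0 of 16694 genes (1243 at an unadjusted p under 0.05, smallest adjusted p 0.616, 58 by DESeq2), and 110 without mKO replicate 2. Between pKO (n = 2) and the controls it called 0 (476 unadjusted, smallest adjusted p 1, 3 by DESeq2). Between KO and mKO it called 0 (2220 unadjusted, smallest adjusted p 0.0822, 405 by DESeq2), and 1044 without mKO replicate 1. Between mKO and pKO it called 0 (1919 unadjusted, smallest adjusted p 0.321, 164 by DESeq2), and 483 without mKO replicate 2. Between KO and pKO 472 genes were higher in KO and 1615 lower. That count of 2087 was 1106, 500 and 954 without KO replicate 1, 2 and 3, 1180 and 582 without pKO replicate 1 and 2 (1 pKO library left, with the spread from the other groups), 3654 by DESeq2 and 0 with the mitochondrial share as a covariate (2414 unadjusted; median absolute log2 fold change 1.77 to 1.46, median SE 0.432 to 0.624). Rises made up 22.6% of the calls, 33.3% with total count scaling and 45.1% by DESeq2. Camera placed ribosome biogenesis downward in mKO against the controls (median log2 fold change -0.50, adjusted p = 1.66e-11) and upward in pKO (0.27, adjusted p = 0.00155), with an adjusted p of 0.509 and 0.777 under an estimated correlation. In mKO it also called cytosolic ribosomal proteins, the proteasome and the translation genes downward and the oocyte genes upward. The mKO libraries split: replicate 1 was lowest in each list called downward, while replicate 2 lay inside the control range of mean log2(CPM + 1) (ribosome biogenesis 6.23, 7.28 and 6.50 in mKO, 7.04 to 7.43 in controls) or, for the proteasome, above it. For the oocyte genes replicates 2 and 3 lay inside it. In pKO it also called cytosolic ribosomal proteins, the spliceosome, the proteasome, oxidative phosphorylation and the cell cycle genes upward. Of both pKO libraries, replicate 2 lay below the controls for ribosomal proteins (8.33 and 7.53, controls 7.57 to 7.67) and inside their range for oxidative phosphorylation (6.05 and 5.56, controls 5.498 to 5.69), and replicate 1 lay inside it for ribosome biogenesis and cell cycle genes. No gene of any of these lists was called in mKO or pKO against the controls, and no call held with an estimated correlation (smallest adjusted p 0.509).

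Genes sorted by their step in the wild-type windows were then followed in the genotype libraries, as sets that share genes. In the libraries labelled KO, 670 of 2011 genes that rise from 24-30hpi to 30-36hpi were lower than in the controls and 2 were higher (median log2 fold change -1.17, camera adjusted p = 1.83e-51, 0.183 with estimated correlation). Of 2501 genes that rise from 18-24hpi to 24-30hpi, 603 were lower and 11 higher (median -0.89, camera adjusted p = 1.25e-29, 0.183 with estimated correlation). Of 3317 genes that fall from 24-30hpi to 30-36hpi, 178 were higher and 1 lower (median 0.71, camera adjusted p = 9.02e-23, 0.183 with estimated correlation). In mKO the 30-36hpi rising set had a median of -0.50 (camera adjusted p = 4.14e-29, 0.225 with estimated correlation), and -0.20 without mKO replicate 1 (camera adjusted p = 3.5e-08). In pKO the same set had a median of 0.24 (camera adjusted p = 1.4e-06, 0.471 with estimated correlation). Camera called 15, 13 and 10 of 18 sets for KO, mKO and pKO against the controls, 5 rather than 13 for mKO without mKO replicate 1, and none with an estimated correlation.

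**Figure D5:**
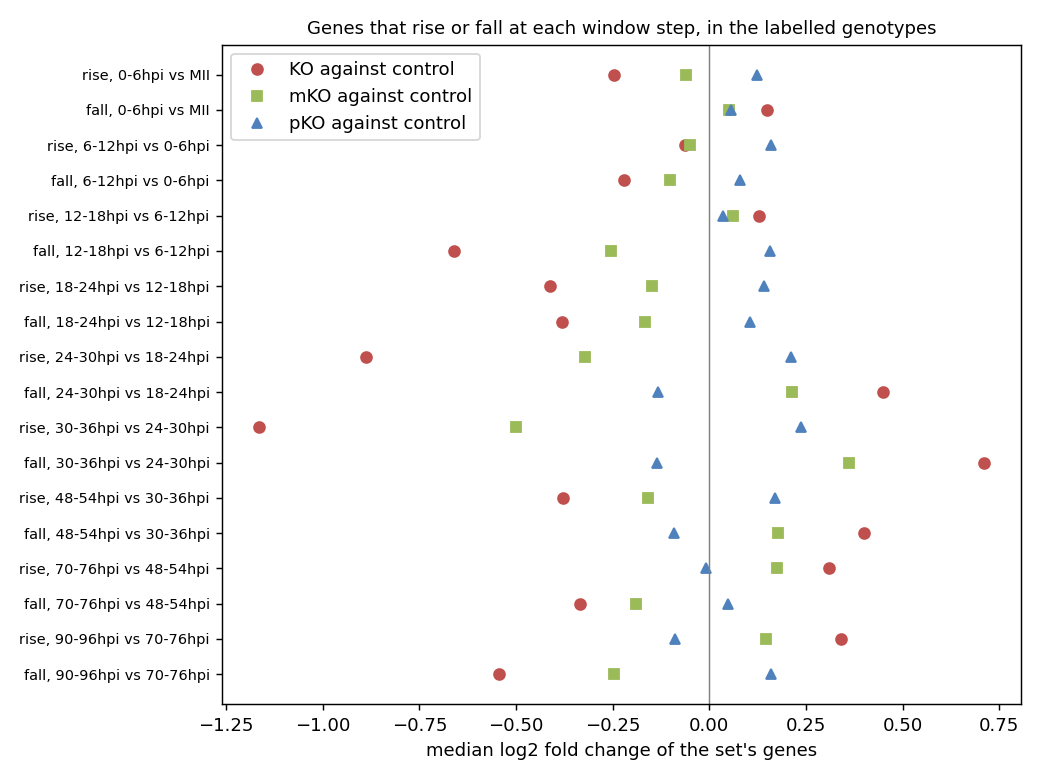
Median log2 fold change, in KO, mKO and pKO libraries against the controls, of the genes that rise or fall at least 2-fold at each step between the wild-type groups. The set that rises from 24-30hpi to 30-36hpi lies at -1.17 in KO, -0.50 in mKO (-0.20 without mKO replicate 1) and 0.24 in pKO.

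The fold changes of KO and mKO against the shared controls had a covariance across genes of 0.815 (0.558 without mKO replicate 1). In 20 simulations of unchanged groups with shared controls it was 0.340 ± 0.012 (SD). The correlation was 0.541 against 0.494 simulated. For KO with pKO the covariance was 0.143 against 0.345 simulated (correlation 0.0832 against 0.435), so this baseline is unsure. For mKO with pKO it was 0.404 against 0.342 (correlation 0.292 against 0.433). KO minus pKO was tested against mKO minus control after the data were seen. By edgeR 0 genes were called (1929 unadjusted, smallest adjusted p 0.357), and no other tool was run.

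The libraries of 10, 40 and 100 embryos (n = 2 each) ask how much input the profiles need. Their replicate pairs correlated at r = 0.906, 0.923 and 0.972 (chi-square per degree of freedom 38.7, 28.3 and 11.03), lowest with 10 embryos. The table is held only in part, with chromosomes 1 to 8, 10, X and part of 14. A fit without 1 library leaves 1 in its group, so its spread comes from the other groups. Of 9132 genes, edgeR called 5 lower with 10 than with 100 embryos and 0 higher (1307 at an unadjusted p under 0.05), against 273 lower and 119 higher by DESeq2 and 283 and 69 by edgeR with no filter. With total count scaling, a replicate block or only the 2 groups 1 gene was called, Folr1. Folr1, a folate receptor, fell from 693 ± 102 to 172 ± 10.3 CPM (log2 fold change -2.01, SE 0.19, adjusted p = 0.00413). Gpx4, a glutathione peroxidase, fell from 2707 ± 53.3 to 1146 ± 158 and H2afz from 9894 ± 1734 to 4206 ± 23.5 CPM. Chosen after their values were seen, because such symbols fall outside the naming rule, 2410024N13Rik was at 48.2 ± 2.43 against 132 ± 7.44 CPM (log2 fold change -1.46, adjusted p = 0.0452) and 2610528J11Rik had an adjusted p of 0.0452. Without 100-embryo replicate 2 Gpx4 and H2afz were not called. Nor were they with total count scaling, a block or only the 2 groups (both adjusted p = 0.0741, 0.125 and 0.0639). Between 40 and 100 embryos 2 genes were higher with 40. Rspo1, an R-spondin, rose from 8.75 ± 0.4898 to 165 ± 55.4 CPM (log2 fold change 4.23, SE 0.47, adjusted p = 0.0238), and Gm26558, also chosen after its values were seen, was at 45.8 ± 18.7 against 2.86 ± 0.294 CPM (adjusted p = 0.0303). Rspo1 was not called without 40-embryo replicate 1 or 100-embryo replicate 1 or 2. Between 10 and 40 embryos edgeR called 4 genes lower with 10 and 0 higher (1589 unadjusted), against 6 lower and 8 higher with total count scaling and 282 and 190 by DESeq2. With a replicate block it called 0 (1421 unadjusted, smallest adjusted p 0.0539), as the median SE of the 4 genes went from 0.223 to 0.243 and their median absolute log2 fold change stayed at 1.73. Rspo1 fell from 165 ± 55.4 to 17.3 ± 12.3 CPM (log2 fold change -3.26, SE 0.45, adjusted p = 0.0437). Xlr5a fell from 76.95 ± 13.7 to 22.3 ± 2.06 and Folr1 from 549 ± 104 to 172 ± 10.3 CPM, beside 2410024N13Rik (log2 fold change -1.57, adjusted p = 0.0416). Rspo1 and Xlr5a were not called without 40-embryo replicate 1, nor Xlr5a with only the 2 groups (adjusted p = 0.106). Xlr5a has near-identical copies, so its value is uncertain.

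Camera called 5 lists between embryo numbers, with no member called. None of the 5 was called with an estimated correlation (smallest adjusted p 0.714) or by fry, whose null is no change in the list (smallest adjusted p 0.201). Fry instead called the chromatin regulators upward with 10 against 100 and 40 embryos (adjusted p = 0.0312 each) and the oocyte genes downward with 10 against 100 (adjusted p = 0.0438). From 100 to 10 embryos, 0 of 7 2-cell-stage genes rose and 0 fell (0 and 1 listwise, camera downward adjusted p = 0.0135, 0.714 estimated). Sp110 measured 20.2 ± 1.03 and 16.9 ± 3.78 CPM (adjusted p = 0.81). 0 of 27 oxidative phosphorylation genes rose and 0 fell (3 and 11 listwise, camera downward adjusted p = 0.00525, 0.714 estimated). Cox6a1 measured 2357 ± 259.6 and 976 ± 224 CPM (adjusted p = 0.0813) and Ndufc2 measured 867 ± 34.7 and 528 ± 42.3 CPM (adjusted p = 0.0842). From 100 to 40 embryos, 0 of 47 cytosolic ribosomal proteins rose and 0 fell (0 and 0 listwise, camera upward adjusted p = 0.00198, 0.714 estimated). Rplp0 measured 5587 ± 762 and 6469 ± 849 CPM (adjusted p = 1) and Rplp2 measured 1238 ± 24.05 and 1297 ± 259 CPM (adjusted p = 1). From 40 to 10 embryos, 0 of 47 cytosolic ribosomal proteins rose and 0 fell (0 and 1 listwise, camera downward adjusted p = 3.85e-05, 0.714 estimated). Rpl15 measured 4427 ± 339 and 2660.3 ± 144 CPM (adjusted p = 0.0955) and Rpl5 measured 3799.7 ± 19.3 and 2683 ± 56.9 CPM (adjusted p = 0.124). 0 of 27 oxidative phosphorylation genes rose and 0 fell (2 and 12 listwise, camera downward adjusted p = 0.0148, 0.714 estimated). Ndufb5 measured 939 ± 48.6 and 557 ± 3.32 CPM (adjusted p = 0.0949) and Ndufs3 measured 358 ± 78.4 and 202 ± 11.2 CPM (adjusted p = 0.105). With total count scaling the oxidative phosphorylation calls were lost (adjusted p = 0.0817 against 100 embryos and 0.211 against 40).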

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

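Thinning, the mitochondrial alternatives, fry for the stage-derived sets, leaving out mKO replicate 1 for these sets and the overlap, and other scalings for the lists were chosen after the data were seen. A minimum absolute log2 fold change of 1 left 1716 genes at 0-6hpi, 543 at 6-12hpi, 879 at 12-18hpi, 3382 at 18-24hpi, 4903 at 24-30hpi and 4164 at 90-96hpi, as its construction makes it. In a fit of only the 2 groups 3577 (6-12hpi), 3628 (12-18hpi) and 3166 (KO against control) were called. For the other changes given here the cause was not tested. With total count scaling the median log2 fold change of all genes moved from 0.03 to 0.19 at 0-6hpi, 0 to 0.12 at 18-24hpi, -0.12 to 0.28 at 24-30hpi, -0.19 to -0.66 at 48-54hpi, 0 to 0.20 at 70-76hpi, 0.07 to 0.17 at 90-96hpi and 0.33 to 0.44 for 12-18hpi against MII. It moved from 0.09 to 0.20 for KO against pKO, 0.02 to 0.16 for mKO against pKO, 0.05 to 0.23 for 10 against 100 and 0.02 to 0.23 for 10 against 40 embryos.

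KO against control gave 2237 genes with no low-count filter, 2064 with a replicate block, 2698 by DESeq2 and 0 with the mitochondrial covariate. KO against pKO gave 3654 by DESeq2 and 0 with that covariate. With no filter and by DESeq2, mKO against control gave 47 and 58, pKO against control 4 and 3, KO against mKO 543 and 405, and mKO against pKO 136 and 164. For 10 against 100 embryos the counts were 1 with total count scaling, a block or only the 2 groups, 352 with no filter and 392 by DESeq2. For 40 against 100 they were 11 with no filter, 1 with a block and 3 by DESeq2. For 10 against 40 they were 10 with DESeq2 size factors, 14 with total count scaling, 394 with no filter, 0 with a block (by edgeR), 472 by DESeq2 and 2 with only the 2 groups.

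With each library left out the counts ran from 2631 to 2901 (0-6hpi), 739 to 871 (6-12hpi), 1201 to 1779 (12-18hpi), 4403 to 4976 (18-24hpi), 6068 to 6894 (24-30hpi), 7251 to 7563 (30-36hpi), 9360 to 9648 (48-54hpi), 6159 to 6490 (70-76hpi), 5304 to 6132 (90-96hpi) and 6234 to 6503 (12-18hpi against MII). They ran from 0 (without KO replicate 2) to 892 for KO against control, 0 to 110 for mKO against control, 0 to 0 for pKO against control, 0 to 1044 for KO against mKO, 500 to 1180 for KO against pKO and 0 to 483 for mKO against pKO. For embryo numbers they ran from 1 to 125 (10 against 100), 0 to 3 (40 against 100) and 2 to 177 (10 against 40). Without a pKO or embryo-number library 1 is left in its group, and the spread comes from the other groups.

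Camera called 77 lists in the windows, 46 in the genotypes and 5 in the embryo numbers. An estimated correlation left 11, 0 and 0, directional fry called 135, 8 and 3, and total count scaling 9 in the embryo numbers. Over 18 stage-derived sets in 6 contrasts camera made 80 calls, against 0 with an estimated correlation, 18 by fry, 56 with sets at a log2 fold change of 2 and 70 without mKO replicate 1. The covariance of KO with mKO was 0.817 with DESeq2 size factors and 0.558 without mKO replicate 1.

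Over all genes that the naming rule selects, printed or not, 336 of 449 called results kept their call in every alternative, and 443 of 6050 values lost it with no change of direction. Of 69 results not called, 16 turned direction in at least 1 alternative. Those printed turned to these log2 fold changes. Klf17 at 12-18hpi against 6-12hpi gave -0.017 to 0.16 (libraries left out). Klf17 at 24-30hpi against 18-24hpi gave 0.26 (total count scaling) and -0.19 to 0.20 (libraries left out). Fgf4 at KO against control gave 0.23 (mitochondrial covariate). Pkm at KO against control gave 0.39 (mitochondrial covariate). Sesn2 at KO against control gave 0.029 (mitochondrial covariate). Klf17 at KO against control gave 0.35 (mitochondrial covariate) and -0.21 to 0.0012 (libraries left out). Klf17 at mKO against control gave 0.015 (mitochondrial covariate) and -0.31 to 0.26 (libraries left out). Klf17 at KO against mKO gave -0.055 (total count scaling), -0.028 (no low-count filter), -0.011 (libraries thinned to one depth) and -0.32 to 0.21 (libraries left out). Rplp2 at 40 embryos against 100 embryos gave -0.16 to 0.25 (libraries left out). Of lists, the OBOX homeobox genes (KO against control, adjusted p 0.836 (replicate block) and 0.998 (DESeq2 size factors)) and the cumulus and granulosa cell markers (KO against control, adjusted p 0.965 (fry)) turned. The alternatives of a labelled share of reads, and of another pseudocount, were not run, since the tables hold 1 kind of count. Pairing by replicate number stays open. In no contrast with at least 3 pairs did all correlate above 0.1 (highest 0.202). With 2 pairs, mKO against pKO had 0.122 and 0.166. A 2-fold change was recovered for 8% of simulated genes between KO and control.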

Other observations

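The tests of the mitochondrial share as a covariate and of both explanations for the first mKO library were chosen after the result was seen. So were the cumulus, sperm and regrouping tests. The position of the KO libraries among the windows was tested after list results and a principal component analysis had been seen, so it is a hypothesis from the same data.

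Between the libraries labelled KO and the controls 1358 genes were called. The tables argue against depth (1318 genes called with libraries thinned to one depth), mitochondrial reads taking counts (1347 without mitochondrial genes) and gene length (Spearman correlation across genes 0.0550). With the mitochondrial share as a covariate edgeR called 0 genes (1424 at an unadjusted p under 0.05), as folds shrank and SEs grew (median SE 0.387 to 0.667). Since that share is higher in each KO library than in each control, sample quality and genotype cannot be told apart. A candidate explanation is an earlier developmental position: fold changes correlated at -0.504 across 15388 genes (which are not independent) with those from 18-24hpi to 30-36hpi, and 2.14% of 4949 genes not called at either step of those windows were called, against 11.9% of the moving genes (3.42% of 994 and 18.1% of 5633 among genes with a mean of at least 20 CPM in the genotype libraries). On that axis KO libraries lay at 0.468 to 0.511 and controls at 0.691 to 0.809 (difference -0.285, two-sided exact permutation p = 0.1, the smallest 3 against 3 can give, adjusted 0.3), and a delay from the genotype and a different time of collection both stay open, untested.

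The mKO libraries spread over that axis, at 0.474 (the first), 0.814 and 0.647 (lowest control 0.691). Klf17 in the first was 359 CPM against 845 and 794. A swap of labels with a KO library is not borne out, as 0 KO libraries lay nearer the controls and the other mKO libraries than the other KO libraries. The first mKO library itself lay nearer the KO mean (distance 155.7) than that of controls and other mKO libraries (175.5). Its depth of 18706230 reads lies inside the range of the other libraries. A single wrong label, a difference in stage or a difference between embryos could each give that, and they were not told apart.

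Between MII oocytes and 0-6hpi 3441 genes were called, and at least 3509 under both other scalings. Whether cumulus cells contribute could not be decided, since the sum of their markers comes nearly all from Cyp19a1. That sum was 44.9 CPM lower at 0-6hpi (difference -44.9, sum of SDs 18.1), with Cyp19a1 at 143 and 98.3 CPM (edgeR adjusted p = 0.0727). Cyp19a1 was still at 86.5 CPM at 6-12hpi and 97.1 CPM at 12-18hpi. By edgeR 0 of 9 markers were called. Without Cyp19a1, computed after that result was seen, the sums were 7.32 and 6.89 CPM. Sperm RNA cannot be told apart from noise between libraries, with a marker sum 34.7 CPM higher at 0-6hpi against a sum of SDs of 36.6, nearly all from Odf2 (210 to 242 CPM). The other 6 markers, computed after that result was seen, summed to 4.31 and 7.66 CPM. A change in the embryo itself was not separated from these.

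For each comparison of 3 libraries with 3, the 6 libraries were regrouped in all 10 ways and fitted alone. The real grouping alone (1 of 10) reached its count for the 10 window contrasts (4443, 3577, 3628, 5314, 7175, 7278, 8656, 6851, 6418 and, for 12-18hpi against MII, 6424) and for KO against control (3166), with a highest other count of 0. For mKO against control and KO against mKO the real count was 0, so 10 of 10 groupings reached it. The splits are too few for a share under 0.05.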
